A study of Mus musculus with 14 samples.

How the data were processed

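RNA sequencing of 14 mouse macrophage libraries was analysed in 2 experiments. In the culture experiment, bone marrow of C57BL/6 mice was grown for 7 days with CSF1, the growth factor that turns marrow monocytes into macrophages, with or without 20 ng/mL IL4, a cytokine of type 2 immunity, giving 4 libraries per group. The growth protocol gives CSF1 at 25 ng/mL and the design text at 20 ng/mL. In the marrow experiment, cells carrying the macrophage surface protein F4/80 were sorted from bone marrow 12 days after transplantation of acute myeloid leukemia (AML) cells that expressed IL4 or an empty vector, giving 3 libraries per group. Per the labels' protocols, RNA was purified with RNeasy Micro columns and libraries were made with the TruSeq RNA v2 kit. Per the submitters' processing notes, bcl2fastq, TopHat2 2.0.13 and the mouse build mm10 were used. The counting tool, the filter on genes, the normalization and the use of strand are not given in the sources used here.

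Each experiment had its own deposited table with 9474 genes, the same genes in both, and the values of a gene in each library. The authors' library values are on a log2 scale, as the values themselves show: in each library they are the log2 of a whole number of reads plus 0.5, shifted by a constant per gene and a constant per library. Solving for these constants gave whole reads in every library for 9406 genes (99.3%), with a largest residual of 0.00065 (log2) where reads were under 100. For the other 68 genes, among them Chil3, Lyz2, Ctsc, Fcgr2b and Aldoa, no reads were recovered and only the log2 values were used. The values are not comparable between genes, because of the constant per gene. The recovered reads sum to 508665 to 842069 per library, with a median of 23 to 41 reads per gene, and 0.361% to 1.69% of genes have 0 reads in a library. The libraries are therefore shallow, and genes with few reads have wide counting intervals. The tables also hold the authors' deposited fold change, a linear ratio, and the authors' deposited p-value and q-value per gene. In the marrow table the deposited fold change is the plain difference of the log2 values. In the culture table it is matched only when a second log2 is taken of the log2 values, and so are the deposited p-values (largest log10 difference 0.00776, against 8.36 without the second log) and the q-values made from them. Fold changes here were computed anew from the library values. No column of per-sample values was left unused (0).

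Before the data were examined, the groups, the tests, the threshold of an adjusted p below 0.05, 32 gene lists (617 genes), the rule for named genes and a first set of alternatives were fixed. That design assumed counts or normalized values on a linear scale, with a pseudocount added before the log. Since the deposited values are already log2, limma with a variance trend was applied to them as they stand, within each table, with no covariate (residual degrees of freedom 6 in culture and 4 in marrow), and p-values were adjusted by the Benjamini-Hochberg method over the 9474 genes. All tests are two-sided. Every adjusted p of a gene is from limma, and n is 4 per group in culture and 3 per group in marrow unless stated. The labels do not say that libraries came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical. In no pair of libraries of a group did the recovered reads differ by as little as sampling noise (chi-square per degree of freedom 1.36 to 5.81), so none was treated as a duplicate. Between-group values are log2 fold changes, IL4 minus control, with their standard errors, or group means with standard deviations on the deposited log2 scale.

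Of the list genes 411 were measured, and 29 lists with at least 3 measured genes were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists. Alternatives were a preset correlation of 0.05, an estimated correlation, ranks, and fry, which tests whether a list's genes move on balance to a single side without comparing them with other genes. Counts of list members that rose or fell use the adjustment over all genes, and counts adjusted over the list alone are given where they differ. The comparison of the experiments used Spearman's rho across genes, Fisher's exact test for shared calls, and, for the difference of the responses, z of the difference of both log2 fold changes over its standard error. The experiments share no libraries. An interaction term in a model over all 14 libraries was added after the data were seen.

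Named genes were taken by rule in each comparison: the 6 largest rises and 6 largest falls past the threshold, without predicted genes, above the 25th percentile of mean level and with no overlap between groups; the 2 changed members with the smallest p of each list that was called or had at least 3 changed members; and always Il4, Il4ra, Stat6, Arg1, Retnla, Chil3, Mrc1, Cd47, Sirpa, Adgre1 and Csf1r. This gave 60 genes in culture and 59 in marrow; the values of some genes are not reported here. Other members of the fixed lists appear as values of their list. Il4 was not analysed here. Adgre1, the gene of F4/80, is Emr1 in the tables, and further older symbols were matched (Rnase2a for Ear11, Siglec5 for Siglecf, Lilrb4 for Lilrb4a, 4632428N05Rik for Vsir, Pf4 for Cxcl4). Positions on mm10 were taken from the GENCODE vM21 annotation by gene symbol, which matched 9419 genes. Ear2 and Rnase2a, Chil3, Bcl2a1b, and Hspa1a and Hspa1b have near-identical relatives whose reads the counting could have divided, so their values are uncertain.

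For a group with 0 reads of a gene, the fold is a bound computed with 3 reads over the group, written as at least N-fold. With 1 to 3 reads in a group, the ratio of recovered reads is given with its exact 95% interval. Fitted log2 fold changes of such genes depend on the 0.5 reads added before the log and are no bounds. Floors and intervals cover counting error only, because the libraries carry no molecular identifiers.

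Alternatives chosen after seeing the data were centring each library on its median, quantile normalization, a pseudocount of 1 on the unlogged values, limma without the variance trend, the trend on recovered reads, voom of limma on recovered reads, a filter of at least 10 recovered reads, the authors' deposited q-values, list counts without the replicate 4 libraries of the culture experiment, the interaction model, and shared calls after centring. Centring was added because the median log2 fold change of all genes was -0.36 in culture.

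The steps were tested on simulated data drawn from the real means and library sizes. In the simulated culture comparison 62% of genes changed 2-fold and 89% of those changed 4-fold were called (100 genes each of 9406), and 7.36% of 163 calls were of unchanged genes. In the simulated marrow comparison these were 44%, 90% and 1.47% of 136 calls. The z test of the difference was too liberal: 23.5% of its 119 calls had no difference, against 5.62% of 89 calls of the interaction term, and of 50 genes changed in opposite directions at each size, z called 84% at 2-fold and 98% at 4-fold and the interaction 70% and 98%. The z count stands as fixed and the interaction count is given beside it. Read recovery on simulated data succeeded for 9373 of 9406 genes, 99.8% of them with every read right. In each simulated comparison 0 of 20 unchanged lists were called, and the raised list was called. The simulated genes were drawn independently of each other, so this could not test lists of genes that vary together. Other splits of the real libraries called up to 11 lists in culture and 8 in marrow. The simulated dispersion sat at its lower limit of 0.01, while the replicate 4 libraries of the culture experiment vary more than that, which raises the simulated power. Far fewer genes were changed in the simulation than the 3838 and 1721 called in the data. This makes the adjustment stricter and lowers the simulated power, so it may be too high or too low. R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table was used, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.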

Results

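The study concerned IL4 and CD47, a surface protein that protects cells from being engulfed, in the phagocytosis of leukemia cells by macrophages. RNA was sequenced from mouse macrophages exposed to IL4 in culture or in leukemic bone marrow. The culture experiment held 4 libraries of macrophages grown with CSF1 and 4 grown with CSF1 and IL4. The marrow experiment held 3 libraries of F4/80-positive cells from mice transplanted with control AML cells and 3 from mice transplanted with AML cells expressing IL4. Recovered reads totalled 842069, 581187, 596105 and 662535 in culture controls 1 to 4, and 749848, 750389, 643479 and 610079 in culture IL4 libraries 1 to 4. In marrow they totalled 618156, 618863 and 662687 in controls 1 to 3, and 531398, 508665 and 768488 in IL4 libraries 1 to 3. Both tables held the same 9474 genes. The 50 genes with most recovered reads took 12.6% to 17.6% of recovered reads in culture controls, 22.2% to 24.0% in culture IL4 libraries and at most 14.3% in marrow libraries. Genes without recovered reads, such as Chil3 and Lyz2, are left out of these totals and shares.

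The first comparison asked how cultured macrophages changed with IL4. Genes of alternative macrophage activation had the largest rises. Retnla, a secreted product of alternatively activated macrophages (chromosome 16:48842551-48844461, plus strand), had 0 reads in each of the 4 controls and 4641 to 11618 in the IL4 libraries, at least 8778-fold higher, with a fitted log2 fold change of 13.52 ± 0.32 (SE, n = 4 per group, limma adjusted p = 1.51e-09). Arg1, the arginase that converts arginine to ornithine and urea (10:24915221-24927484, minus strand), had 0 to 1 reads in controls and 1714 to 8497 with IL4, a ratio of 23850 (95% interval 4280 to 942045). Chil3, a chitinase-like secreted protein, rose by 12.58 ± 0.35 on the log2 scale (adjusted p = 6.9e-09). All positions are on mm10. Cx3cr1, the fractalkine receptor of monocytes and macrophages (9:119901616-120069879, minus strand), had 154 to 286 reads in controls and 0 in all 4 IL4 libraries, at least 331-fold lower.

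Of the 29 measured genes of the IL4 alternative activation list 25 rose, 1 fell and 3 did not pass. The median log2 fold change was 3.32, and camera called the list up (adjusted p = 2.63e-31; adjusted p = 0.000293 with an estimated correlation). The ribonuclease genes Rnase2a (log2 fold change 10.04 ± 0.22, at least 725-fold) and Ear2 (9.74 ± 0.60, ratio 1409, interval 390 to 11639) rose, as did the lectin gene Mgl2 (9.79 ± 0.21, at least 602-fold) and Pdcd1lg2, a ligand of PD-1 (7.64 ± 0.28, ratio 537, interval 96.0 to 21252). The cytokine signalling inhibitor Cish rose by 5.26 ± 0.47 and the chemokine gene Ccl24 by 5.11 ± 0.67. Fcrls fell (-1.52), and 2 genes fell without IL4 library 4. Mrc1, the mannose receptor gene (2:14229392-14332057, plus strand), did not pass (0.14, adjusted p = 0.648), nor did Cd163 (-1.48, adjusted p = 0.126).

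In all, 3838 genes passed in culture, of which 754 rose and 3084 fell. The median log2 fold change over all genes was -0.36, a 0.779-fold level. After each library was centred on its median, 2570 genes passed, 1365 up and 1205 down, and quantile normalization gave 2595, 1271 up and 1324 down. Counts after centring are therefore given for the lists in which they differ. The groups did not overlap in 3573 of the 9474 genes, where chance gives 2.86% of genes.

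Of the antigen presentation and metabolic lists, 4 were called up with IL4 in culture. Of 11 genes of MHC class II presentation 8 rose and 0 fell (camera adjusted p = 1.02e-08; adjusted p = 0.139 with an estimated correlation), among them the invariant chain gene Cd74 (3.92 ± 0.44, adjusted p = 0.000124), H2-Aa (3.82), the regulator Ciita (2.65) and the thiol reductase gene Ifi30 (1.19 ± 0.13). Of 16 glycolysis genes 14 rose and 0 fell (1.95e-15; adjusted p = 0.139 with an estimated correlation), including the phosphofructokinase gene Pfkp (1.83 ± 0.15), the lactate dehydrogenase gene Ldha (1.71 ± 0.16) and the glucose transporter gene Slc2a1 (2.93). In the glycolysis score, IL4 library 4 lay at 0.01 and the other IL4 libraries at 0.83 to 0.94. Without that library 15 genes rose, and without control 4, 13 did. Of 23 genes of lipid uptake, oxidation and PPAR targets 11 rose and 0 fell, 11 and 1 adjusted over the list alone and 13 and 0 after centring (2.55e-08; adjusted p = 0.139 with an estimated correlation), with the desaturase gene Scd2 (3.54 ± 0.21), the cholesterol exporter gene Abca1 (1.82 ± 0.26) and the nuclear receptor gene Pparg (1.59). In this list 1 gene fell without control 4 and 2 without IL4 library 4. Of 10 genes of arginine and polyamine metabolism 4 rose and 1 fell, 5 and 0 after centring (0.000513; adjusted p = 0.0734 with an estimated correlation). The arginine transporter genes Slc7a2 (7.23 ± 0.39) and Slc7a1 (1.40) rose with Arg1, and Asl fell (-0.63; not past the threshold after centring, adjusted p = 0.358, and 0 genes of the list fell without control 4 or without IL4 library 4).

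Of 11 osteoclast genes 6 rose and 2 fell, 7 and 2 after centring (3.55e-05; adjusted p = 0.0480 with an estimated correlation). The integrin gene Itgb3 (4.34 ± 0.15), the collagen-degrading cathepsin gene Ctsk (4.53 ± 0.29) and the acid phosphatase gene Acp5 (4.36) rose, while Nfatc1 (-1.57) and the RANK gene Tnfrsf11a (-1.33) fell. Of 45 lysosome and phagosome genes 14 rose and 8 fell, and 19 rose and 3 fell after centring. The list was called up (0.000211; adjusted p = 0.296 with an estimated correlation) although its median was -0.04 and its mean 0.33, and Ctsl (1.49) and Psap (1.36) were among the genes that rose while Ctsc (-2.53 ± 0.23) and the NADPH oxidase gene Cybb (-1.19) fell. Of 15 genes of the integrated stress response, the program driven by ATF4, 3 rose and 0 fell, and 8 and 0 after centring (0.000159; adjusted p = 0.139 with an estimated correlation). Trib3 (3.08 ± 0.51), the cystine transporter gene Slc7a11 (2.97 ± 0.46) and Ddit3 (1.26) rose, and Atf4 did not pass (0.21). The score of this list in IL4 library 4 was -0.28, against 0.53 to 0.63 in the other IL4 libraries. Without that library 9 genes rose and 1 fell, and without control 4 the counts were 3 and 0.

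Genes of cell division fell in culture. Of 30 cell cycle genes 28 fell and 0 rose, 29 and 1 adjusted over the list alone and 23 and 1 after centring (camera adjusted p = 1.02e-05; adjusted p = 0.595 with an estimated correlation; fry adjusted p = 0.00564). Mki67, which marks dividing cells (7:135689784-135716361), went from a mean of 7.70 ± 0.94 in controls to 4.62 ± 0.62 with IL4 (SD, log2; log2 fold change -3.08 ± 0.44), and the kinetochore gene Cenpf fell by 2.92 ± 0.43. The replicate 4 libraries stood apart in this list, with scores of -0.22 in control 4 against 1.48 to 1.73 in the other controls, and -0.60 in IL4 library 4 against -1.49 to -1.18. Without control 4, 29 genes fell and 1 rose, and without IL4 library 4, 28 fell and 0 rose. Of 19 stress and dissociation genes 5 rose and 7 fell, 6 and 9 adjusted over the list alone and 7 and 5 after centring (camera up, adjusted p = 0.678, with a median of -0.41). The immediate early genes Fos (-1.88 ± 0.12) and Ier2 (-2.30 ± 0.15) fell, and the chaperone gene Hspa1a (1.98) and Atf3 (1.92) rose. IL4 library 4 had a stress score of -0.54 and the others -0.06 to -0.01. The counts were 6 and 8 without it and 5 and 8 without control 4.

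Among 24 interferon response genes 17 fell and 2 rose, 18 and 3 adjusted over the list alone and 15 and 3 after centring. The list's camera adjusted p was 0.0408 (adjusted p = 0.595 with an estimated correlation and 0.176 at a preset correlation of 0.05), and it was 0.0996 without control 1, 0.0590 without control 4 and 0.119 without IL4 library 4. The antiviral gene Oas2 fell by 6.05 ± 0.56, with a ratio of reads of 95.4 (interval 32.3 to 465), and Rtp4 by 5.39 ± 0.65, while Gbp2 (2.44) and Usp18 (2.12) rose. Of 8 classical activation genes 4 fell and 0 rose, 3 and 0 after centring (down, 0.187; 0.0303 after centring), including the inflammasome gene Nlrp3 (-3.11 ± 0.20) and Nfkbiz (-3.44 ± 0.54).

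Of 18 macrophage identity genes 11 fell and 4 rose, 11 and 6 after centring (down, 0.290; 0.0421 after centring). Emr1, the F4/80 gene (17:57358691-57483527, plus strand), fell by 1.17 ± 0.14 (adjusted p = 0.000218; -0.81 after centring), and Csf1r, the CSF1 receptor gene (18:61100598-61132149, plus strand), by 0.96 ± 0.14 (0.000544; -0.60 after centring), while Lgals3 (1.44) and Gpnmb (1.21) rose. Of 17 bone marrow resident macrophage genes 8 fell and 2 rose, 8 and 3 adjusted over the list alone and 8 and 4 after centring (down, 0.460). The iron exporter gene Slc40a1 fell by 7.22 ± 0.83 and the receptor tyrosine kinase gene Axl by 4.56 ± 0.42. The transcription factor gene Maf fell by 4.33 ± 0.23 (adjusted p = 1.27e-06), and the sialoadhesin gene Siglec1 fell (-1.85). Among the largest falls of single genes were the scavenger receptor gene Stab1 (-6.45 ± 0.22), Itgal, an integrin of leukocytes (-5.02 ± 0.42), and the inhibitors of differentiation Id3 (-5.78 ± 0.44) and Id1 (-4.71 ± 0.41).

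Cd47 (16:49800533-49915010, plus strand) was 1.28-fold higher with IL4 in culture, at 10.11 ± 0.13 in controls and 10.47 ± 0.10 with IL4 (SD, log2), a log2 fold change of 0.35 ± 0.11 (adjusted p = 0.0321). It had 69 to 119 reads in controls and 103 to 142 with IL4. The adjusted p was 0.0522 without control 1, 0.0988 without control 3, 0.0882 without IL4 library 1, 0.0579 without IL4 library 2, 0.0514 without IL4 library 4 and 0.0622 without the variance trend, and 0.00159 after centring, where the log2 fold change was 0.72. Sirpa, the gene of the macrophage receptor for CD47 (2:129592835-129632228, plus strand), fell from 9.66 ± 0.06 to 8.72 ± 0.07, 1.92-fold (-0.94 ± 0.10, adjusted p = 8.62e-05; -0.58 after centring, adjusted p = 0.00248). Of 23 inhibitory phagocytosis checkpoints 5 rose and 9 fell, 5 and 6 after centring (up, 0.678, with a median of -0.23). The PD-L1 gene Cd274 (2.78) rose, and Siglece (-3.67) and Havcr2 (-3.17), inhibitory receptors, fell. Of 37 engulfment receptors and machinery genes 11 rose and 21 fell, and 13 rose and 15 fell after centring (down, 0.739). Itgb3, Fcgr2b, the inhibitory Fc receptor gene (2.11 ± 0.17), and Mfge8, a bridge to dying cells (3.27), rose, and the complement gene C1qa (-2.28), the receptor gene Mertk (-1.47), its ligand gene Gas6 (-3.54) and the Fc receptor gene Fcgr1 (-2.91) fell.

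Il4ra, the IL4 receptor alpha chain gene (7:125552120-125579474, plus strand), fell from 6.19 ± 0.22 to 5.06 ± 0.08 (-1.13 ± 0.14, adjusted p = 0.000211; -0.77 after centring), and Stat6, the transcription factor it activates, did not pass (-0.16, adjusted p = 0.238). Of 13 genes of the IL4 receptor and STAT6 signalling list 2 rose and 5 fell, 2 and 2 after centring (up, 0.947, with a median of -0.54 and a mean of 0.16). The feedback inhibitor gene Socs1 (3.56) and Cish rose and the phosphatase gene Ptpn6 fell (-1.56 ± 0.12). Without IL4 library 4, 2 rose and 3 fell. Of 9 chemokines 3 rose and 5 fell, 3 and 4 after centring (up, 0.739, with a median of -1.60). Ccl6 rose (2.51 ± 0.18) and Pf4 fell (-3.08 ± 0.34). Of 15 chemokine and adhesion receptors 3 rose and 7 fell, 5 and 7 after centring (down, 0.579), with Itgax rising (5.03) and Ccr2, the receptor for CCL2 (-3.63), and Itga6 (-2.71 ± 0.20) falling. Of 22 cholesterol synthesis genes 3 rose and 1 fell, 5 and 0 after centring (up, 0.232, with a median of -0.31). Sqle (0.92 ± 0.17) and Dhcr7 (1.21 ± 0.27) rose. The counts were 3 and 7 without IL4 library 4 and 3 and 2 without control 4, and the camera adjusted p was 0.0490 without IL4 library 1. Of 26 oxidative phosphorylation genes 0 rose and 4 fell, 0 and 3 adjusted over the list alone, but 5 rose and 1 fell after centring (up, 0.460, with a median of -0.05; 0.0456 after centring). Ndufa4 fell (-0.76; -0.39 after centring), and Idh2 (-0.77) did not pass after centring (-0.41, adjusted p = 0.0951).

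Markers of other cell types were few among the genes of both tables: 7 of 16 monocyte, 6 of 20 neutrophil and 3 of 17 B cell markers were measured. The same markers were measured in culture and in marrow, so their small number says nothing about which cells were present. Of 7 monocyte markers 2 rose (Chil3, and the fibronectin gene Fn1 by 3.09 ± 0.28) and 3 fell, 2 and 4 adjusted over the list alone, with Ccr2 and F13a1 (-2.39) among the latter (up, 0.449, with a median of -1.94, -1.70 with genes at their bounds, and a mean of 0.68). Of 3 megakaryocyte and platelet markers Itgb3 and Vwf (3.00) rose and Pf4 fell (up, 0.0198; adjusted p = 0.139 with an estimated correlation, 0.480 by ranks, 0.0715 with the replicate block and 0.147 after centring). The score of IL4 library 4 was 0.22, against 0.83 to 0.90 in the others. Of 6 neutrophil markers 1 rose and 1 fell, 1 and 3 adjusted over the list alone and 1 and 0 after centring, and 1 and 2 without control 4 or without IL4 library 4 (up, 0.739, with a median of -1.28). Of 5 eosinophil markers Ear2 rose and 0 fell, or 1 without IL4 library 4 (up, 0.137). Of 3 B cell markers Cd22 (1.52 ± 0.36) and Blnk (0.39) rose and Cd79b (-2.38 ± 0.26) fell (up, 0.429, with a mean of -0.16). Of 3 dendritic cell markers Mgl2 rose, and Bst2 (-1.51) and Irf8 (-0.82; adjusted p = 0.124 after centring) fell (up, 0.522, with a median of -0.82 and a mean of 2.49), with 1 and 1 after centring. Of 6 progenitor and leukemic blast markers 1 rose and 3 fell, including Cd34 (-3.68 ± 0.51; ratio of reads 19.6, interval 6.38 to 98.1), with the list down (0.678). Of 4 endothelial and stromal markers the adhesion gene Pecam1 rose (4.29; ratio of reads 35.6, interval 9.53 to 300) and the collagen genes Col1a1 (-3.04 ± 0.30) and Col1a2 (-3.12 ± 0.31) and Sparc (-3.45) fell (down, 0.522). In lists too small to test, the erythroid markers Car2 (4.11) and Tfrc (2.41) and the T cell marker Il7r (2.08) rose, and the mast cell marker Gata2 did not pass (1.08, adjusted p = 0.157).

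**Figure D1:**
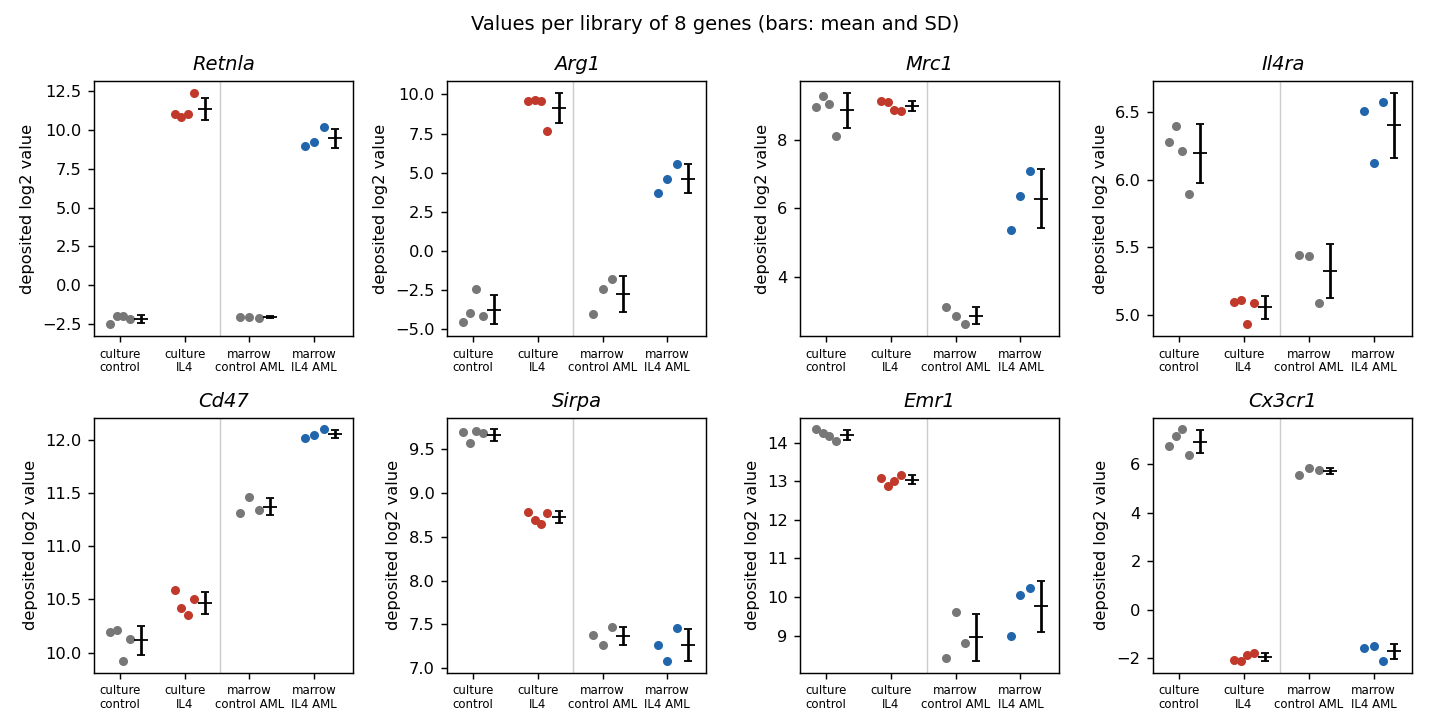
Deposited log2 values of Retnla, Arg1, Mrc1, Il4ra, Cd47, Sirpa, Emr1 and Cx3cr1 in each of the 14 libraries, with bars for the mean and SD of each group; values are not comparable between genes. Il4ra lay lower with IL4 in culture (5.06 against 6.19) and higher with IL4 in marrow (6.40 against 5.33), and Cd47 lay higher with IL4 in both.

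The second comparison asked how F4/80-positive marrow cells differed when the transplanted AML cells expressed IL4. Genes of alternative activation rose here too. Retnla had 0 reads in each of the 3 controls and 895 to 3037 in the 3 IL4 libraries, at least 1585-fold higher (log2 fold change 11.53 ± 0.32, SE, n = 3 per group, limma adjusted p = 2.37e-07). Arg1 rose by 7.38 ± 0.66, a ratio of reads of 255 (interval 86.9 to 1239), and Mrc1 went from 2.86 ± 0.25 to 6.28 ± 0.87 (SD, log2; log2 fold change 3.43 ± 0.38, adjusted p = 0.000488). C1qb, a chain of complement C1q (4:136880129-136886187), rose by 3.44 ± 0.33 (adjusted p = 0.000255), and Mertk, a receptor for dying cells, by 3.90 ± 0.69 (adjusted p = 0.00479). The monocyte markers Ccr2 (9:124101950-124113557; -3.92 ± 0.16, adjusted p = 3.83e-06) and Fn1 (1:71585520-71653200; -4.20 ± 0.34) fell, and so did Cx3cr1 (at least 88.1-fold lower).

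Of the 29 alternative activation genes 18 rose, 2 fell and 9 did not pass, 21 and 2 adjusted over the list alone and 19 and 2 after centring (camera adjusted p = 2.72e-15; adjusted p = 0.168 with an estimated correlation). Rnase2a (fitted log2 fold change 7.38 ± 0.53), Ccl24 (at least 74.8-fold), Slc7a2 (6.97 ± 0.64; ratio of reads 194, interval 53.4 to 1608), Pparg (4.19 ± 0.53), Cish (3.64 ± 0.24) and Chil3 (2.95 ± 0.14) rose, and the transcription factor genes Irf4 (-1.54 ± 0.18) and Klf4 (-1.45 ± 0.16) fell. Il4ra rose 2.10-fold, from 5.33 ± 0.20 to 6.40 ± 0.24 (1.07 ± 0.18, adjusted p = 0.00344), and Stat6 did not pass (0.24, adjusted p = 0.306). Of 13 genes of IL4 receptor and STAT6 signalling 3 rose and 1 fell, 3 and 0 after centring (up, 0.0264; adjusted p = 0.244 with an estimated correlation, 0.0774 at a preset correlation of 0.05, 0.0634 by ranks and 0.0620 without IL4 library 3). In all, 1721 genes passed in marrow, of which 635 rose and 1086 fell, and 1740 after centring, 895 up and 845 down (median over all genes -0.06). The count was 1147 without control 2 and 1104 without control 3. The groups did not overlap in 3560 of the 9474 genes, where chance gives 10% of genes, more than in culture.

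Of 17 bone marrow resident macrophage genes 10 rose and 1 fell, 11 and 1 adjusted over the list alone (up, 1.22e-07; adjusted p = 0.244 with an estimated correlation). Together with C1qa (2.77 ± 0.39), C1qc (3.49 ± 0.48) and Mrc1, the fatty acid binding protein gene Fabp4 (4.02 ± 0.47), Axl (2.34 ± 0.45), the hemoglobin scavenger gene Cd163 (2.33), Siglec1 (2.09) and the adhesion gene Vcam1 (1.13) rose. Slc40a1 did not pass (0.07, adjusted p = 0.832). The list scores were -0.99 to -0.80 in controls and 0.21, 1.08 and 1.41 in the IL4 libraries. Of 7 monocyte markers 5 fell and 1 rose (down, 0.00277; adjusted p = 0.244 with an estimated correlation). Ccr2, Fn1, the coagulation factor gene F13a1 (-4.27 ± 0.39), Ms4a4c (-1.87) and Nr4a1 (-2.22) fell, and Chil3 rose. Of 18 macrophage identity genes 8 fell and 1 rose, 8 and 2 adjusted over the list alone and 6 and 1 after centring (down, 0.0766; 0.0365 after centring and 0.0254 without IL4 library 3). Csf1r fell by 1.17 ± 0.28 (adjusted p = 0.0193; 0.0705 without control 2, 0.0578 without control 3 and 0.0554 without the variance trend), and the lysozyme gene Lyz2 (-2.28 ± 0.15) and Apoe (-1.51) fell. Emr1, whose protein was the sort marker, did not pass (0.81 ± 0.36, adjusted p = 0.153). Its adjusted p was 0.0240 with the replicate block, 0.0163 with voom, 0.0324 with the trend on recovered reads and 0.0352 without IL4 library 1.

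**Figure D2:**
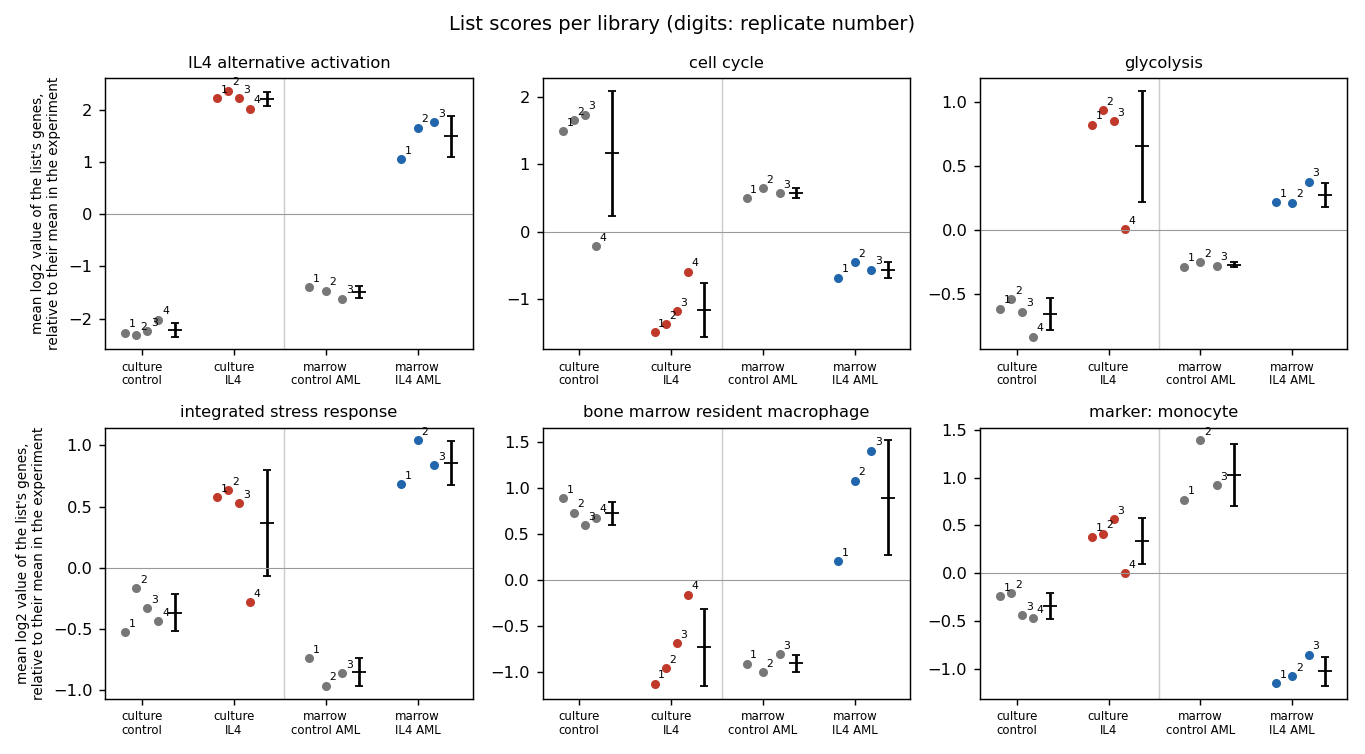
Mean scores of 6 gene lists in each library, grouped by experiment and treatment, with digits for the replicate. In marrow the resident macrophage score was -0.99 to -0.80 in controls and 0.21 to 1.41 with IL4, and in culture the cell cycle score of control 4 (-0.22) lay apart from the other controls (1.48 to 1.73).

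Cd47 was 1.60-fold higher in marrow with IL4, at 11.37 ± 0.08 in controls and 12.05 ± 0.04 with IL4 (0.68 ± 0.12, adjusted p = 0.00532), with 184 to 206 reads against 259 to 408. It passed under every alternative run, with adjusted p between 2.55e-05 and 0.0284. Sirpa did not pass, at 7.37 ± 0.11 and 7.27 ± 0.19 (-0.10, adjusted p = 0.659). Of 23 inhibitory phagocytosis checkpoints 7 rose and 5 fell, 8 and 5 both adjusted over the list alone and after centring (up, 0.280, with a mean of -0.03). Cd274 (2.16 ± 0.47), the CD200 receptor gene Cd200r1 (1.60 ± 0.15) and Havcr2 (2.34) rose. Thbs1, a secreted ligand of CD47 (2:118111876-118127133), fell by 7.89 ± 0.63, a ratio of reads of 612 (interval 109 to 24207), and Cd24a, a surface glycoprotein gene, by 0.94 ± 0.14. Of 37 engulfment receptors and machinery genes 11 rose and 7 fell, 12 and 9 adjusted over the list alone and 12 and 6 after centring (up, 0.109). Beside the C1q chains, Mertk and Axl, Fcgr2b (2.46 ± 0.20) and Itgb3 (1.66 ± 0.18) rose, and Lrp1, a receptor for calreticulin (-2.83 ± 0.27), Fcgr1 (-2.70 ± 0.33), the scavenger receptor gene Stab1 (-1.65) and Slamf7 (-1.98) fell.

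Of 30 cell cycle genes 26 fell and 0 rose in marrow, 28 and 0 adjusted over the list alone (camera adjusted p = 2.58e-17; adjusted p = 0.168 with an estimated correlation; fry adjusted p = 0.000892). Mki67 went from 9.71 ± 0.15 to 8.10 ± 0.22 (-1.62 ± 0.15) and Cenpa fell by 1.70 ± 0.17. Of 15 integrated stress response genes 14 rose and 0 fell (1.46e-12; adjusted p = 0.115 with an estimated correlation), among them Trib3 (5.81 ± 0.61), the asparagine synthetase gene Asns (2.10), Sesn2 (1.84 ± 0.22) and Atf4 (0.96). Of 19 stress and dissociation genes 8 fell and 0 rose, 8 and 3 adjusted over the list alone and 8 and 1 after centring (down, 0.00363; adjusted p = 0.318 with an estimated correlation), with Fos (-2.49 ± 0.21), Fosb (-2.38 ± 0.28) and Hspa1a (-2.78) falling.

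Of 23 genes of lipid uptake, oxidation and PPAR targets 9 rose and 1 fell, 13 and 1 adjusted over the list alone and 11 and 1 after centring (5.4e-06; adjusted p = 0.244 with an estimated correlation), including Angptl4 (2.87 ± 0.31) and the lipid droplet gene Plin2 (1.65 ± 0.13), while Scd1 fell (-2.37). Of 16 glycolysis genes 6 rose and 0 fell, 9 and 1 adjusted over the list alone and 8 and 0 after centring (2.9e-05; adjusted p = 0.120 with an estimated correlation), with the hexokinase gene Hk3 (1.58 ± 0.14) and the aldolase gene Aldoa (0.97 ± 0.14). Of 10 arginine and polyamine genes 4 rose and 2 fell, 4 and 1 after centring (0.0197; adjusted p = 0.283 with an estimated correlation, 0.0526 at a preset correlation of 0.05 and 0.0799 by ranks). Odc1, the first enzyme of polyamine synthesis, fell (-0.91). Of 11 MHC class II genes 4 rose and 1 fell, 6 and 2 adjusted over the list alone and 5 and 1 after centring (0.0312; adjusted p = 0.402 with an estimated correlation, 0.0774 at a preset correlation of 0.05, 0.0656 by ranks, 0.0551 without control 1 and 0.0930 without IL4 library 2), with Cd74 (1.47 ± 0.29) and H2-Aa (1.38 ± 0.22) rising. Of 22 cholesterol synthesis genes 8 fell and 0 rose, 12 and 0 adjusted over the list alone (0.000492; adjusted p = 0.244 with an estimated correlation), with Msmo1 (-1.08 ± 0.17) and Cyp51 (-1.52) falling. Of 26 oxidative phosphorylation genes 0 rose and 1 fell, Ndufa4 (-0.43; adjusted p = 0.0787 after centring), with 0 and 0 both adjusted over the list alone and after centring (down, 0.866).

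Of 45 lysosome and phagosome genes 8 rose and 9 fell, 9 and 12 adjusted over the list alone and 9 and 6 after centring (up, 0.733, with a median of -0.04). The proton pump gene Atp6v0d2 (5.23 ± 0.59) and Cd63 (1.57 ± 0.15) rose, and Cybb (-1.55 ± 0.12) and Ctsh (-1.37) fell. Of 24 interferon response genes 5 fell and 0 rose, 8 and 0 adjusted over the list alone and 3 and 0 after centring (down, 0.0657; 0.0479 after centring, 0.0444 without control 2 and 0.0153 without IL4 library 2). Rsad2 fell by 2.17 ± 0.27, and Cmpk2 (-1.13) lost its call without control 1, control 3, IL4 library 1 or IL4 library 3 and without the variance trend. Of 8 classical activation genes 2 fell, Irf5 (-1.26) and Nlrp3 (-1.62), and 0 rose, with 3 and 0 adjusted over the list alone (down, 0.0864). Of 11 osteoclast genes 2 rose and 1 fell (up, 0.801, with a median of -0.19). Of 9 chemokines Ccl24 and Ccl6 (1.47 ± 0.15) rose and Ccl2 (-2.71) fell (up, 0.109). Of 15 chemokine and adhesion receptors 3 rose and 4 fell, 5 and 5 adjusted over the list alone and 5 and 3 after centring (up, 0.900, with a median of 0.18 and a mean of -0.42), including Pecam1 (2.05 ± 0.25) up and Itga4 (-1.56) down.

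Markers of further cell types also moved in the sorted marrow cells, again with only part of each list measured. All 3 B cell markers fell (Blnk -2.84 ± 0.29, Cd79b -1.47 ± 0.20 and Cd22 -1.13; camera adjusted p = 0.00277; adjusted p = 0.244 with an estimated correlation). Of 4 endothelial and stromal markers Col1a2 (2.41 ± 0.51; ratio of reads 8.17, interval 1.92 to 73.3), Pecam1 and Sparc (1.60) rose, and Col1a1 did not pass (0.50; list up, 0.00452; adjusted p = 0.244 with an estimated correlation). Of 5 eosinophil markers Ear2 (1.77 ± 0.31) and Prg2 (1.22 ± 0.20) rose and Cd24a fell (up, 0.144). Of 6 neutrophil markers Ngp fell (-0.89) and 0 rose (down, 0.700). Of 6 progenitor and leukemic blast markers Gata2 (2.08 ± 0.18) rose and Mef2c (-2.18 ± 0.25), Sox4 (-1.38) and Cd93 (-0.76; adjusted p = 0.0689 after centring) fell, 2 and 3 adjusted over the list alone and 1 and 2 after centring (down, 0.733), and Cd34 did not pass (0.23, adjusted p = 0.738). Of 3 megakaryocyte markers Itgb3 rose (up, 0.0910; 0.0231 without IL4 library 2), and of 3 dendritic cell markers Mgl2 rose and Irf8 (-2.19) fell (down, 0.941, with a median of -0.40 and a mean of 1.09). Outside the tested lists the erythroid markers Car2 (-3.66) and Tfrc (-2.15) and the T cell marker Il7r (-2.98) fell, and the mast cell marker Gata2 rose. Among the largest changes of single genes, the phosphatase gene Ptpn3 (5.22 ± 0.49; ratio of reads 46.0, interval 15.4 to 226), the aminopeptidase gene Anpep (4.24 ± 0.45; ratio 41.9, interval 7.11 to 1694), the growth factor gene Hgf (3.95 ± 0.36) and Bcl2a1b (3.78 ± 0.56) rose. The water channel gene Aqp1 (-5.07 ± 0.25), the B cell regulator gene Bach2 (-4.44 ± 0.45) and Ifi27l2a (-4.14 ± 0.30) fell.

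**Figure D3:**
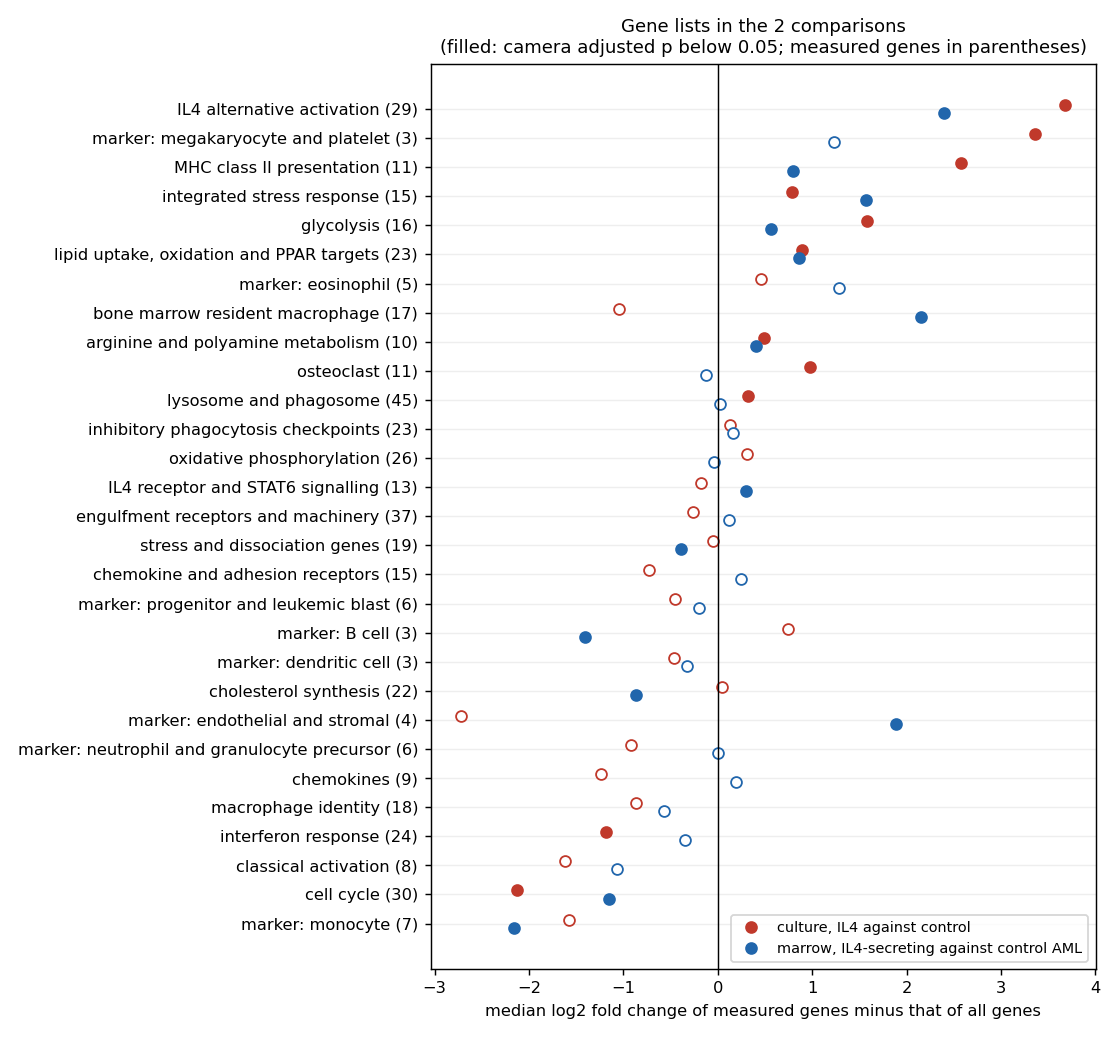
Median log2 fold change of each list's measured genes minus that of all genes, in culture and in marrow, with the number of measured genes in parentheses; filled points mark a camera adjusted p below 0.05. Camera called 11 lists in culture (9 up, 2 down) and 14 in marrow (9 up, 5 down). With an estimated correlation it called 2 in culture and 0 in marrow.

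The third comparison asked whether the changes with IL4 in culture and in marrow were alike. The experiments also differ in the cells, the sort, the leukemia and the source of IL4. A difference between them therefore cannot be told apart from these factors and need not be a different response of macrophages to IL4. Retnla, Arg1, Mgl2, Slc7a2 and Cish rose in both and Cx3cr1 and Ccr2 fell in both. The fold changes of the experiments were weakly related across the 9474 genes (Spearman's rho 0.203, Pearson's r 0.289; genes are not independent replicates). Calls in the same direction were more frequent than for independent lists: 166 genes rose in both, where 50.5 would be shared by independent lists (Fisher's exact p = 1.2e-47), and 555 fell in both, where 354 would be (p = 2.82e-41 by the same exact test). Fisher's test counts genes as independent, so these p-values do not measure the spread between samples. Without marrow control 3, 365 fell in both. After centring, 299 rose in both and 288 fell in both. A further 83 genes rose in culture and fell in marrow (86.4 for independent lists), and 149 fell in culture and rose in marrow (207). Among genes called in both, 75.7% moved the same way. Falls outnumbered rises in each experiment, which by itself raises this share.

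The responses differed in 3005 genes by z, 803 with a higher and 2202 with a lower change in culture, and in 2186 by the interaction term. After each experiment's fold changes were centred on their median, z gave 2456 genes, 1272 higher and 1184 lower in culture. Il4ra fell in culture and rose in marrow, a difference of -2.21 (culture minus marrow, log2; interaction adjusted p = 1.51e-05). C1qb likewise differed by -4.84 (2.44e-06), and Axl by -6.90, both falling in culture and rising in marrow. Mrc1 rose in marrow and did not pass in culture, with a difference of -3.29 (0.000218), and Sirpa fell in culture, with a difference of -0.84 (0.00145). Fn1 rose in culture and fell in marrow, a difference of 7.30. The change of Cd47 was not shown to differ between the experiments (-0.33, adjusted p = 0.123 by z and 0.140 by the interaction). After centring, its change was 0.72 in culture and 0.79 in marrow. Differences of single genes are given without centring and carry the shift of the medians over all genes (-0.36 in culture and -0.06 in marrow). Of the lists called different, that of resident macrophages had the largest median difference (median of the gene differences -3.82, interaction adjusted p = 3.77e-05; adjusted p = 0.294 with an estimated correlation).

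**Figure D4:**
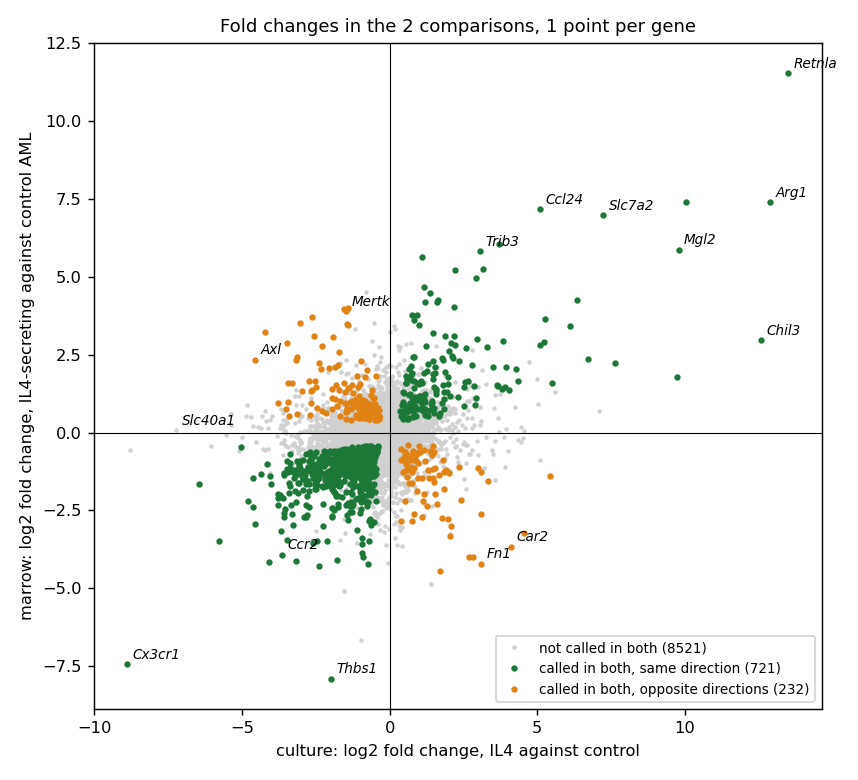
Log2 fold change of each of the 9474 genes in culture (x axis) against marrow (y axis), 1 point per gene. Of these, 721 were called in the same direction in both, 232 in opposite directions and 8521 were not called in both.

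At this depth changed genes could have been missed: in simulation 62% of genes changed 2-fold were called in culture and 44% in marrow. The shares in the real data may be higher or lower. With an estimated correlation, camera called 2 lists in culture and 0 in marrow, where the lowest adjusted p was 0.115. In culture and marrow, 8 and 4 lists had an unadjusted p below 0.05, and fry called 23 and 20.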

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

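The tests of the 3 patterns weighed here, the interaction term for genes and lists, and the split counts for changed genes were chosen after the results were seen. Split counts for lists, for rho, for the difference and for shared calls were chosen before.

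The authors' deposited culture fold changes differ from the differences of the deposited library values, by a median of 0.31 and by up to 5.74 (log2), and in sign for 118 genes (1.25%). In the authors' deposited table the fold of Cd47 was 1.03 (q = 0.0280) against 1.28 from the values, that of Sirpa 0.903 against 0.521 and that of Il4ra 0.817 against 0.455. Rounding of the library values is argued against by the largest difference of 5.74. A second log2 taken of values already on a log2 scale, with a floor of 0.01, matched 9474 of 9474 genes within 0.001, where a single log matched 19, and the deposited p-values, on which the q-values rest, within 0.00776 (log10), where a single log differed by up to 8.36. This is consistent with a processing step of the culture table alone, since the marrow table was matched by a single log to within 6.81e-07.

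In culture control 4 the cell cycle score was -0.22, against 1.48 to 1.73 in the other controls. An exchange with an IL4 library is argued against by its alternative activation score of -2.02, near the other controls (-2.32 to -2.24) and far from the IL4 libraries (2.02 to 2.37, so none was out of place as a partner); the bound of this test was changed after its value had been seen. Its Retnla reads allow at most 0.0460% of RNA from IL4-treated cells, and its depth of 662535 reads lay within that of the other controls (581187 to 842069), which argues against a mixture or low depth. IL4 library 4 also stood apart from its group, and the deviations of both replicate 4 libraries from their group means correlated by -0.05 across genes; a batch was not tested further and stays open. No biological explanation was tested, since the labels name no difference between replicates.

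In marrow, 10 of 17 resident macrophage genes rose and 1 fell (list median 2.09), while 5 of 7 monocyte markers fell and 1 rose (list median -2.22; adjusted p = 0.244 with an estimated correlation for each list). A lower share of monocytes as the cause of both would raise the markers of every other type alike, if those types kept their proportions among themselves. The highest neutrophil marker, Csf3r, had 0.44 (list median -0.07, SD 0.49), and all 3 B cell markers fell (list median -1.47). The medians of endothelial and stromal (1.83), eosinophil (1.22) and megakaryocyte markers (1.17) lay above 0. These markers moved both ways, and the proportions of these types in the sort are not known, so this test cannot decide. Depth is argued against by a ratio of mean reads of 0.952 with overlapping ranges (508665 to 768488 and 618156 to 662687). A response like that of cultured macrophages is argued against for the resident genes only. Their median was -1.40 in culture (camera adjusted p = 0.460), and they differed by -3.82 (interaction adjusted p = 3.77e-05, and 0.294 with an estimated correlation). The cultured cells are not those of the marrow, so a response of marrow macrophages to IL4 was not tested. For the monocyte markers that culture response cannot be told apart, because of the 5 that fell in marrow 2 fell and 1 rose in culture, with a median of -1.94. More resident macrophages among the F4/80-sorted cells, fewer monocytes, or a change of expression within either may each contribute and stay open. The share of AML cells among the sorted cells was not tested.

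Single libraries of the culture groups stood far from the other 3 of their group in 17 of 182 tests, where chance gives about 1 in 20, and 12 of the 17 were replicate 4 libraries. In control 4, Itgal was at 6.32 (others 5.93 to 5.98, log2 values), Mki67 at 6.30 (8.09 to 8.27), Cenpf at 5.03 (6.48 to 6.71), Ndufa4 at 8.20 (8.61 to 8.66) and the cell cycle score at -0.22 (1.48 to 1.73). Control 2 had Nfkbiz at 3.91 (2.84 to 2.89) and Sirpa at 9.57 (9.69 to 9.70), and control 1 had Pdcd1lg2 at 0.0546 (-1.18 to -0.98). In IL4 library 4, Retnla was at 12.41 (10.87 to 11.07), Ldha at 8.34 (8.96 to 9.08) and Arg1 at 7.67 (9.60 to 9.68). Its scores were 0.00761 for glycolysis (0.83 to 0.94), -0.54 for stress and dissociation genes (-0.06 to -0.01), -0.28 for the integrated stress response (0.53 to 0.63) and 0.22 for megakaryocyte markers (0.83 to 0.90). IL4 library 1 had Cd34 at -2.45 (-0.87 to -0.57), and IL4 library 3 had Il4ra at 4.93 (5.09 to 5.12).

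The change with IL4 differed between culture and marrow in 10 lists by camera on the interaction term. The median of the gene differences, culture minus marrow in log2, was 1.62 for alternative activation (adjusted p = 2.01e-05; adjusted p = 0.0633 with an estimated correlation), 1.62 for MHC class II presentation (2.68e-05; 0.294) and 0.74 for glycolysis (2.01e-05; 0.320). It was -3.82 for resident macrophage genes (3.77e-05; 0.294), 0.74 for cholesterol synthesis (3.77e-05; 0.320), 0.39 for osteoclast genes (0.000627; 0.0563) and 1.31 for monocyte markers (0.000608; 0.0563). It was 0.13 for lysosome and phagosome genes (0.00775; 0.364), 0.18 for stress and dissociation genes (0.0342; 0.467) and 2.65 for B cell markers (0.0264; 0.312). The second p of each pair is the adjusted p with an estimated correlation, and none of these passed 0.05.

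Of 96 named genes 65 differed between culture and marrow by the interaction term (adjusted p between 3.1e-08 and 0.0388), and 72 by z. Those called in opposite directions had differences (culture minus marrow, log2) of -6.90 for Axl, 7.30 for Fn1, 2.65 for Cd22, -5.53 for Col1a2, -2.21 for Il4ra, -5.49 for Hgf, 6.13 for Bach2, -4.84 for C1qb, 7.77 for Car2, 3.22 for Blnk and 2.70 for Mef2c. Among alternative activation and signalling genes the differences were 1.98 for Retnla, 9.63 for Chil3, 2.66 for Rnase2a, 3.93 for Mgl2, 7.97 for Ear2, 5.42 for Pdcd1lg2, 5.51 for Arg1, -3.29 for Mrc1 and -1.66 for Ptpn6. Among macrophage and engulfment genes they were -7.29 for Slc40a1, -4.79 for Stab1, -4.87 for Maf, -0.84 for Sirpa, -1.98 for Emr1, 2.20 for Lrp1, 5.92 for Thbs1, 2.68 for Itgb3, 4.72 for Ctsk, -1.98 for Ctsc and -1.79 for Cd93. Inflammatory, interferon and antigen presentation genes had -1.49 for Nlrp3, -2.99 for Nfkbiz, -5.62 for Oas2, -5.64 for Rtp4, 2.85 for Rsad2, -1.12 for Bst2, 1.41 for Ifi30, 2.45 for Cd74 and 2.43 for H2-Aa. Receptor and chemokine genes had -1.46 for Cx3cr1, -4.55 for Itgal, -2.90 for Itga6, 2.24 for Pecam1, 1.05 for Ccl6 and -4.25 for Pf4. Metabolic genes had 2.21 for Sqle, 1.65 for Dhcr7, 1.19 for Msmo1, 2.74 for Scd2, -0.83 for Plin2, -2.13 for Angptl4, 0.75 for Pfkp, 1.10 for Ldha and -1.10 for Idh2. Further differences were -2.30 for Id3, -5.19 for Id1, -2.03 for Ier2, -2.73 for Trib3, -3.91 for Cd34, -3.54 for Col1a1, -3.00 for Ptpn3, -2.60 for Anpep and -2.85 for Bcl2a1b. Retnla had no reads in the controls of either experiment, and Cx3cr1 none in the IL4 libraries of either. Their fitted changes depend on the reads added before the log, so whether their responses differed cannot be decided. Both are counted among the 65. Rnase2a and Mgl2 had no reads in the culture controls, so the sizes of their differences were not measured. Genes with 1 to 3 reads in a group, for which a ratio of reads with an interval is given, have uncertain sizes too. Arg1, Ear2, Pdcd1lg2, Oas2 and Thbs1 are among them. For Chil3 no reads were recovered, so whether its control values lay at the floor is not known.

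Other splits of the libraries were counted for each main result. In culture 1 of the 35 splits, the real one, gave as many as 3838 genes (highest other 1), a share under 0.05. Every other split puts IL4 and control libraries in the same group, which widens the spread within groups and lowers its count. The count was therefore rare among splits, but chance is not excluded by it. As many as 11 lists came in 3 of the 35 splits (highest other 11), so chance is not excluded for the number of lists either. In marrow the 10 splits are too few for a share under 0.05: the real split gave 1721 genes and 14 lists, each in 1 split, and the highest others 0 and 8. Of 100 drawn regroupings within both experiments, 2 had an absolute rho as large as 0.203 (highest other 0.206). A rho of this size was therefore rare among regroupings but not absent. As many as 3005 differences by z came in 1 of the 100 (highest other 2464). Regrouping breaks the response in both experiments, so it cannot test whether the responses differ, and no conclusion is drawn for that count. The 166 shared rises and 555 shared falls were each reached in 1 of the 100 (highest other 0), but with 0 genes called in every other marrow split no regrouping of marrow could share a call, so these counts say nothing about chance.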

How the results depend on the processing

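Alternatives added after seeing the data were centring, quantile normalization, a pseudocount of 1, the variance trend settings, voom, the filter of 10 reads, the authors' deposited q-values and the interaction model. List counts without the replicate 4 libraries of the culture experiment were added then too. The rest were chosen before. Of the 3838 genes in culture, 2096 passed an adjusted p of 0.01, 1729 also changed at least 2-fold and 315 passed a Bonferroni adjustment; of the 1721 in marrow these were 820, 963 and 109. Both counts are smaller by construction. The authors' deposited q-values gave 2786 in culture (2650 also called here) and 698 in marrow (646 also called here), and recomputing q from the deposited p gave 698 in marrow too. The culture q-values rest on values logged again. The deposited marrow p-values were matched within 5.61e-05 (log10) by a test of each gene's library values with its own variance only, so the lower count there comes from the test and not from the values or the adjustment. Leaving out a library gave 2995 to 4004 genes in culture and 1104 to 1460 in marrow (1147 without control 2, 1104 without control 3), where fewer samples remain. With an estimated correlation camera called 2 lists in culture and 0 in marrow (lowest adjusted p 0.115), and with log2 fold change as the ranking statistic 18 and 20. Leaving out a library gave 10 to 12 and 13 to 15 lists. Shared rises numbered 86 with a 2-fold change, 299 after centring and 127 to 175 without a library, and shared falls 239, 288 and 365 to 582 (365 without marrow control 3); centring removes the median shift of the culture values. Spearman's correlation across genes ran from 0.190 to 0.213 and differences by z from 2714 to 3336 without a library, with 2084 at 0.01, 2456 after centring and 2186 by the interaction term. Centring turned the balance of directions from 754 up and 3084 down to 1365 and 1205 in culture, from 635 and 1086 to 895 and 845 in marrow, and from 803 and 2202 to 1272 and 1184 for the difference by z. No named gene or list that was called in the settings reported took the opposite sign under an alternative run. Over the 177 results for single genes and lists, 54 comparisons with an alternative lost the call, 27 gained it and 2560 did neither. Same-numbered libraries shared only a number: their deviations correlated by -0.05 to 0.02 in culture and 0.03 to 0.06 in marrow, where each correlates best with its own number, a hint from the data and not the design. With the replicate block, 3447 genes passed in culture and 1764 in marrow, 10 and 14 lists were called, and blocking in culture or in marrow gave 163 or 178 shared rises, 534 or 551 shared falls and 3078 or 3130 differences; rho stayed at 0.203. Apart from the megakaryocyte list in culture and Emr1 in marrow, the block changed no call of a named gene or list. The count model planned for deposited counts was not run, since the deposited values are log2; voom on the recovered reads gave 3919 genes in culture and 2315 in marrow. In addition, no filter on low values was applied, so that leaving out the filter changed nothing. Depth, at most 842069 reads per library over the 9406 genes with recovered reads, limits genes of few reads most.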

Other observations

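The genes in this part were chosen after their values were seen. Beside the fixed lists, several genes rose strongly in both experiments: the coagulation factor gene F7 (log2 fold change 6.35 in culture and 4.26 in marrow), the adhesion gene Bcam (3.69 and 6.03), the alanine aminotransferase gene Gpt2 (2.94 and 4.96), the Ral activator gene Rgl1 (3.84 and 2.93), the IL36 receptor gene Il1rl2 (5.22 and 2.91) and the prolyl hydroxylase gene Egln3 (5.08 and 2.82). Ifi27l2a (-4.08 and -4.14), the apolipoprotein gene Apoc2 (-3.48 and -3.45) and the nucleosome binding gene Hmgn3 (-3.27 and -2.95) fell in both. These were among 166 genes that rose in both and 555 that fell in both.

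Of the 232 genes called in opposite directions, the transferrin receptor gene Tfrc (2.41 in culture and -2.15 in marrow), the carbonic anhydrase gene Car2 (4.11 and -3.66), the cytokine receptor gene Il6st (2.02 and -1.30), the ubiquitin ligase gene Cblb (3.10 and -1.28) and Irf4 (3.32 and -1.54) rose in culture and fell in marrow. Spata13 (-2.65 and 1.33) and Aatk (-2.67 and 0.95) did the reverse.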
